A study of Arabidopsis thaliana with 12 samples.

How the data were processed

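Transcript levels were measured with oligonucleotide arrays in 12 samples of Arabidopsis thaliana, Columbia background, 1 array for each of 3 genotypes in 4 tissues. The tissues were flowers of stages 1-10, 11-12 and 13-14 and a stem piece of about 0.5 cm, taken from untreated plants after 6 weeks of long days. Total RNA was isolated with TRIzol and biotin-labelled cRNA was hybridised. Per the labels, the authors made the deposited values with MAS5, whose version is not given in the sources used here. The deposited unit is a signal intensity on a linear scale, 1 value per probe set and array, and the values show that each array had been scaled globally: the mean of each array after removal of 2% of the values at each end lay between 500.03 and 500.04. The number of arrays limits the precision.

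Sample titles name the intermediate genotype arf6/arf6 ARF8/arf8, whereas the description of the design names it ARF6/arf6 arf8/arf8. Under either reading these plants keep 1 functional copy of ARF6 and ARF8 together, and they are called single-copy plants here. The titles' name is kept.

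Arrays were rescaled to a trimmed mean of 500, which moved no log2 value by more than 0.000128, and values were transformed as log2(signal + 50). Of 22810 probe sets, 64 control probe sets were left out, and 17642 of the other 22746 were kept because their signal reached 100 in at least 1 library. Gene names come from the probe table supplied for the platform, joined to a gene annotation by locus. That table lists 14016 probe sets, of which 13513 belong to 1 gene and 503 to several, and 8730 probe sets that are not controls are not listed. Among the kept probe sets, 9806 had 1 locus, for 9703 different loci. No probe set is listed for ARF6 or ARF8, so their transcript levels were not analysed here. No genomic positions are given.

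Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method over all kept probe sets, with a threshold of 0.05 and two-sided tests. Because no genotype and tissue had a second array, stages 11-12 and 13-14 served together as older flowers, and stage 1-10 flowers and stem as younger tissue. A first model held genotype by phase plus tissue within phase. It gave the differences of both mutants from wild-type and from each other in older flowers, the arf6 arf8 difference from wild-type in younger tissue, and the difference between these effects. A second model held genotype plus tissue and gave the arf6 arf8 difference over all 4 tissues and the difference between stages 13-14 and 1-10 over all 3 genotypes. Libraries are not replicate cultures: the residual spread mixes array error with differences of the genotype effect between tissues, and the p-values measure that spread alone.

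Within single tissues, where no test was possible with 1 array per genotype, probe sets were counted whose ratio of (signal + 50) reached 2 with a signal of 200 or more in the brighter library. The single-copy comparison with wild-type, counted the same way, was planned as its background. Single-copy plants are mutant too and 2 of their arrays stood apart, so this background does not measure array error alone. Gene lists with at least 3 kept members were tested with camera (preset correlation 0.01), again with camera and an estimated correlation, and with fry. Fry was run as a directional test and as a mixed test of change in either direction. Where fry is named alone, the directional test is meant. Within a tissue, the median of a list was placed among those of 10000 random lists matched on mean signal. Of 25 lists written before the data were examined, 9 had enough members in the probe table. Among those not tested were jasmonate response (0 of 23 members kept), jasmonate biosynthesis (2 of 17) and floral organ identity (1 of 17). The lists of SAUR genes (0 of 22) and auxin response factors (0 of 15) were not tested either, and 3 of 25 Aux/IAA genes were kept. Jasmonate and auxin genes are therefore covered only in part. A further 18 lists, called added lists, were written after it was seen which genes the probe table holds and before any genotype difference was looked at, and 17 of them were tested. Each family of lists was adjusted separately, the first over the 9 lists tested and not, as first intended, over all 25.

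The comparisons, tests, filters, 25 lists, alternative settings and the rule for naming genes were fixed before the data were examined. The rule names, for each tested difference, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold. Each must have the same sign in every tissue or genotype averaged, a probe set of 1 gene and a mean signal of 200 or more in the brighter group. It also names list members, up to 4 in each list described, and the 6 highest and 6 lowest ratios of arf6 arf8 to wild-type in each tissue with a signal of 500 or more. ARF6 and ARF8 stood in the rule too, but it could not be met for them.

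The methods were tested on simulated data, in which 200 of 17642 probe sets were given a known change. For arf6 arf8 against wild-type in older flowers, 10% of the changes of 1 log2 unit and 89% of those of 2 log2 units were recovered, none in the wrong direction (0), with 7 calls among unchanged probe sets. Over 4 tissues the recovery was 77% and 99%, with 10 such calls. In the stage comparison it was 52% and 97%, also with 10 such calls. The noise was independent and normal with the spread of the second model, and no simulated array stood apart. Recovery and calls among unchanged probe sets may differ where more genes change or arrays deviate. Of 20 unshifted simulated lists, 0 passed camera with either correlation or directional fry, and the shifted list passed all. These lists held random probe sets with independent noise, and the mixed test was not run on them. They do not show how the tests behave where members vary together. In the measured lists the estimated correlation reached 0.651, for late pollen genes.

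The alternative settings were the values without rescaling, quantile normalization, pseudocounts of 16 and 200, no filter, a filter of 200 in at least 3 libraries, eBayes without trend, flower libraries alone, no block for tissue, a ratio of 3, a brighter signal of 500, and each library left out in turn. A pair of alternatives was chosen after seeing the data: fits without the single-copy libraries of stages 1-10 and 13-14, and fits without all 4 single-copy libraries. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.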

Results

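The arrays compared flowers and stems of wild-type plants, of single-copy plants and of the arf6 arf8 double mutant, which is mutated in the genes of a pair of auxin response factors, transcription factors through which auxin controls gene expression. Each of the 3 genotypes was sampled once as stage 1-10, stage 11-12 and stage 13-14 flowers and once as stem, so there are no replicates within a genotype and tissue. After the deposited scaling to a common trimmed mean, which makes arrays alike in brightness, the 12 arrays had median signals from 192 to 235.3. Between 63.3% and 66.6% of probe sets had a signal of 100 or more. Across genes, which are not independent replicates, the log2 signals of arf6 arf8 and wild-type had Pearson's r of 0.966 in stage 1-10 flowers, 0.910 at stages 11-12, 0.876 at stages 13-14 and 0.945 in stem. The single-copy libraries of stages 1-10 and 13-14 stood apart from wild-type, with 936 and 1012 probe sets differing at least 2-fold, compared with 397 at stages 11-12 and 166 in stem. The single-copy stage 13-14 array also had the lowest GAPDH 3' to 5' ratio of the 12, 0.655, the others lying between 0.922 and 1.61. Its actin 3' to 5' ratio was 5.63, within the 4.96 to 7.13 of all 12. That ratio was 7.09 and 5.49 in wild-type and 5.44 and 4.96 in arf6 arf8 at stages 11-12 and 13-14. The single-copy arrays of stages 1-10 and 13-14 were the extremes of the 12 on hybridisation control transcripts and 25S rRNA. Their bioB was 386.3 at stages 1-10 and 133.1 at stages 13-14 (168 to 266.2 in the others), and 25S rRNA was 179.8 and 41.5 (51.2 to 147.2).

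The first question was which transcripts depend on these auxin response factors in maturing flowers, taken as arf6 arf8 against wild-type at stages 11-12 and 13-14. Transcripts of SWEET9 (AT2G39060), the sugar transporter needed for nectar secretion, fell by 4.60 on the log2 scale (SE 0.378, adjusted p = 0.000899). Its signal was 1310 and 5520 at the 2 stages in wild-type, and 46.7 and 83.9 in arf6 arf8. The sugar transporter gene SWEET14 fell by 3.83 (SE 0.272, adjusted p = 0.000481), the expansin gene EXPA8, whose product loosens cell walls, fell by 3.87 (SE 0.405, adjusted p = 0.00236), and the terpene synthase genes TPS24 (AT3G25810) and TPS11 (AT5G44630) fell by 3.99 and 3.97 (SE 0.369 and 0.371, adjusted p = 0.00143 and 0.00152). Of the genes that rose, AT1G16950 rose by 4.31 (SE 0.361, adjusted p = 9e-04), from signals of 8.9 and 220.8 in wild-type to 1661 and 3619. GID1A, which encodes a gibberellin receptor, rose by 2.17 (SE 0.235, adjusted p = 0.00265), and the expansin-like gene EXLB1 rose by 2.55 (SE 0.276, adjusted p = 0.00265).

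Further genes whose products act on cell walls fell: the pectate lyase gene AT5G48900 (-4.28), AT5G11420 of the DUF642 family of wall proteins (-4.45), and AT1G70720 of the pectin methylesterase inhibitor family (-4.08). The peroxidase gene AT1G44970 fell from a signal of 3841 to 63.8 at stages 11-12, a fitted difference of -4.93 (SE 0.211, adjusted p = 6.71e-05, the smallest of all probe sets). AT1G30795 and AT1G75300 fell by 4.69 and 4.11, whereas AT4G35690 rose by 3.34. The adjusted p of these 7 genes lay between 6.71e-05 and 0.00264. Together with the 8 genes named before them, they stayed past the threshold whichever of the 12 libraries was left out.

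**Figure D1:**
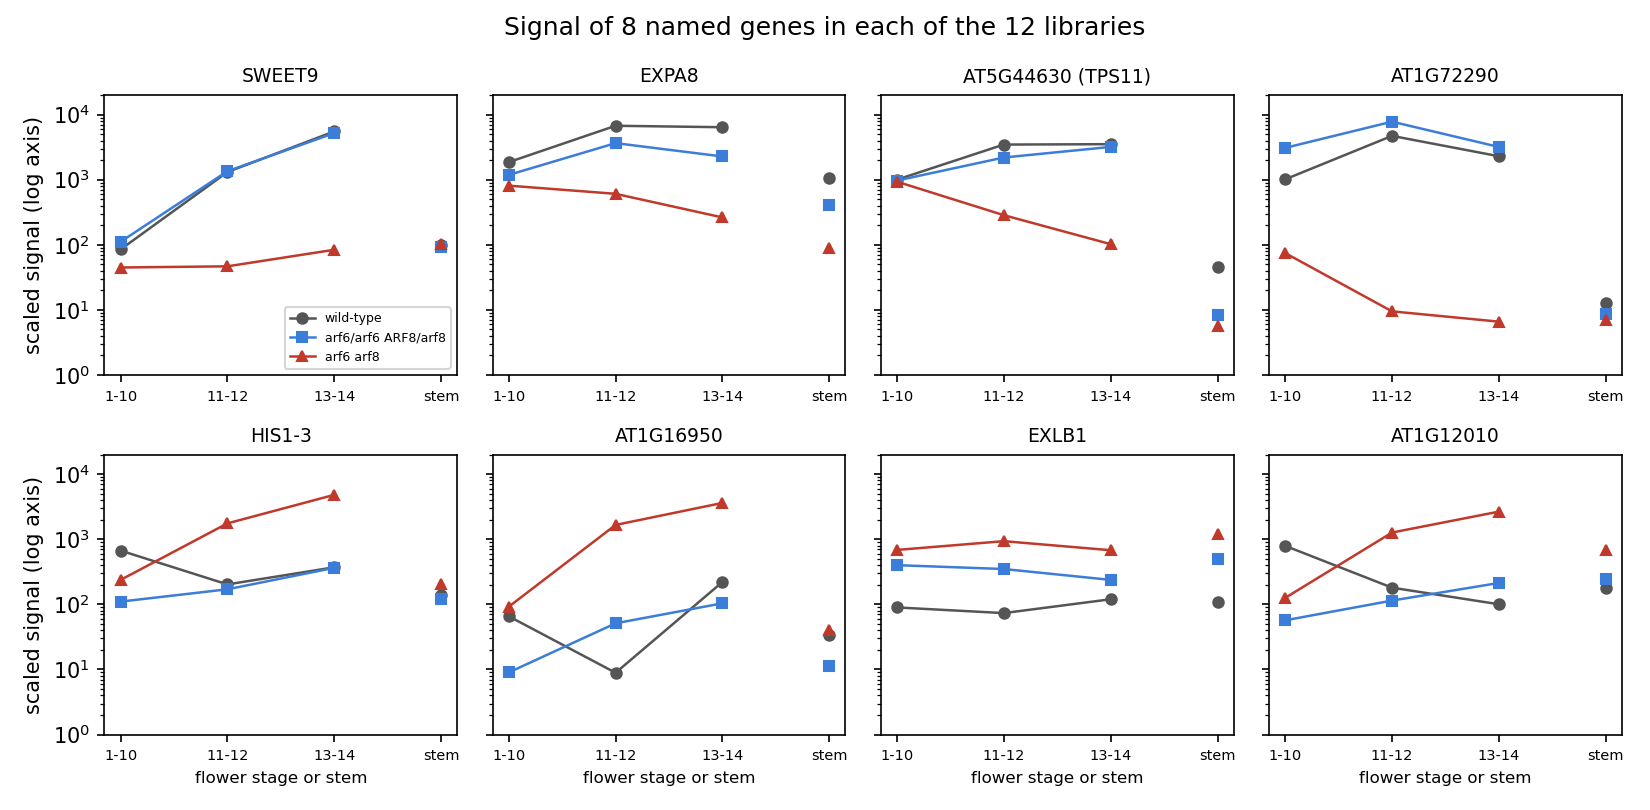
Scaled signal (log axis) of 8 genes in the 12 libraries, with a line for each genotype over flower stages 1-10, 11-12 and 13-14 and a separate point for stem. In stage 13-14 flowers SWEET9 reads 5520 in wild-type, 5201 in single-copy and 83.9 in arf6 arf8, whereas AT1G16950 reads 220.8, 103.9 and 3619.

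Other large changes in older flowers rested on fewer libraries. AT1G72290, a Kunitz-type gene for a chlorophyll-binding protein, fell by 5.85 (SE 0.849, adjusted p = 0.00833), with signals of 4712 and 2293 in wild-type and 9.5 and 6.6 in arf6 arf8. The cytochrome P450 gene CYP71B31 fell by 5.54 (SE 0.83, adjusted p = 0.00935), and so did the xyloglucan-modifying enzyme gene XTH19 (-3.60, SE 0.634, adjusted p = 0.0166) and AT3G12000 (-4.51, SE 0.642, adjusted p = 0.00762). The linker histone gene HIS1-3 rose by 3.18 (SE 0.435, adjusted p = 0.00656), AT2G05540 by 3.02, FMO by 2.84, AT3G53980 by 2.77, and AT1G12010, an ACC oxidase gene of ethylene synthesis, by 3.34 (SE 0.81, adjusted p = 0.0494). AT1G62510, AT1G76960, AT2G20670 and AT3G45680 rose by 2.32 to 2.70. Without the wild-type stage 13-14 library each gene of this paragraph lost its call except AT3G53980, which lost it without the wild-type stage 11-12 library (adjusted p = 0.0548). The other calls ended with an adjusted p of up to 0.385 for AT1G12010 when 1 library was left out, most of them also without the wild-type stage 11-12 library or the arf6 arf8 library of stage 11-12 or 13-14. In flower libraries alone the calls of CYP71B31, XTH19, AT1G62510, AT2G20670 and AT3G45680 ended, and those of AT1G12010 and AT3G45680 did so with a pseudocount of 16 or without a filter. That of AT1G12010 also ended with eBayes without trend and without the single-copy libraries, both the 2 that stood apart and all 4.

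Among the lists written before the data were examined, expansin and XTH genes, which loosen and remodel cell walls, were lower as a group. All 6 measured members were below 0 (median -1.07, mean -1.78), EXPA8 and XTH19 fell, the other 4 did not pass the test, and 5 passed when adjusted over the list alone. The camera adjusted p was 0.00059, and adjusted p = 0.829 with an estimated correlation. Without the arf6 arf8 stage 13-14 library the list's median was -0.56 and its camera adjusted p 0.108. In the larger added family of 22 expansin and XTH genes (median -0.75), 3 fell, EXPA8, XTH19 and XTH16 (-1.48), and 2 rose, EXLB1 and XTH32 (0.90), with a camera adjusted p of 0.00162 and adjusted p = 0.664 with an estimated correlation. That call ended without the wild-type (adjusted p = 0.0801) or the arf6 arf8 (adjusted p = 0.136) stage 13-14 library.

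Sugar transporter genes of the SWEET family, an added list, fell in 5 of 16 members and rose in 0 (median -0.54, camera adjusted p = 0.0155, adjusted p = 0.489 with an estimated correlation). SWEET9 and SWEET14 were joined by SWEET7 (-1.67), SWEET13 (-1.52) and SWEET3 (-1.43). SWEET10 differed the other way by 1.60, with an adjusted p of 0.0519. Of 5 terpene synthase genes (median -1.05), TPS24 and TPS11 fell and the other 3 did not pass the test (camera adjusted p = 0.0149, adjusted p = 0.489 with an estimated correlation). Without the 4 single-copy libraries the list's camera adjusted p was 0.0537.

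Jasmonate-linked genes (10 measured, added list, median -0.33) included 3 that fell and 0 that rose: JMT (-2.06), which encodes the enzyme that methylates jasmonate, JRG21 (-1.48) and GRX480 (-1.16). The camera adjusted p was 0.151 and adjusted p = 0.534 with an estimated correlation, whereas fry, which asks whether the members moved one way, gave 0.0134. Among lists that passed camera in older flowers, fry gave an adjusted p of 0.154 for the 6 expansin and XTH genes, 0.287 for their larger family, 0.677 for pollen, 0.274 for tapetum and sporogenous and 0.348 for plastid-encoded genes, and 0.00175, 0.0134 and 0.0472 for SWEET, terpene synthase and nuclear photosynthesis genes. Of the 4 GH3 genes, whose products conjugate hormones to amino acids (median 0.65, camera adjusted p = 0.42), GH3.5 (WES1) rose by 2.07 and 3 passed when adjusted over the list alone. Of 15 auxin response genes, an added list (median 0.16, camera adjusted p = 0.988), WES1 and the homeobox gene HAT2 (2.0, adjusted p = 0.0304) rose. Fry's mixed test, which does not compare a list with other genes, gave this list an adjusted p of 0.00594. By that test 1 of the 9 fixed and 10 of the 17 added lists passed. Among them were floral organ growth regulators (adjusted p = 0.000636), female gametophyte genes (0.00594) and secondary wall genes (0.00594). Of 20 floral organ growth regulators, also added, BPEp (-1.35), which limits petal size, and YAB5 (-1.30) fell, and the list's median of 0.01, mean of -0.06 and downward camera test (adjusted p = 0.778) differed in sign.

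All 18 nuclear photosynthesis genes, an added list, lay above 0 (median 0.30), and 1 of them, NdhS (0.85), a subunit of the chloroplast NDH complex, rose (camera adjusted p = 0.00162, adjusted p = 0.534 with an estimated correlation). The 42 plastid-encoded genes had a median of 0.27 with 0 past the test (camera adjusted p = 0.0266, adjusted p = 0.664 with an estimated correlation). Anther lists were lower: 36 pollen genes had a median of -0.14 with 1 member fallen, the sperm histone gene MGH3 (-1.54), and 13 tapetum and sporogenous genes had a median of -0.32 with 0 fallen (camera adjusted p = 0.0155 and 0.0266, adjusted p = 0.79 and 0.534 with an estimated correlation). Without the arf6 arf8 stage 13-14 library the camera calls of the nuclear photosynthesis (adjusted p = 0.0609), plastid-encoded (0.512), pollen (0.676) and tapetum (0.0504) lists ended. Calls ended as well without the wild-type stage 13-14 library for plastid-encoded genes (0.178), and without the wild-type (0.336) or arf6 arf8 (0.0726) stage 11-12 library and with quantile normalization (0.0615) for the tapetum list.

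The remaining lists did not pass camera. Their medians were -0.50 for 3 Aux/IAA genes, -0.24 for 3 auxin synthesis and transport genes, -0.11 for 7 late pollen genes, -0.45 for 3 tapetum and pollen wall genes and -0.09 for 3 flavonoid genes, with 0 members past the test over all genes and 1, 0, 1, 1 and 0 adjusted over the list alone. Among 3 gynoecium genes CES (-1.61), a bHLH regulator of carpel development, fell, and 2 passed when adjusted over the list alone, with a median of 0.14, a mean of -0.30 and a downward test. The 3 reference genes had a median of 0.18 and a mean of 0.03 with a downward test (adjusted p = 0.977). In added lists the medians were -0.19 for 14 cell division genes (camera adjusted p = 0.0808), -0.11 for 6 secondary wall genes, of which IRX15-L (-1.16) fell, -0.21 for 8 senescence genes and -0.05 for 7 cold and dehydration genes. Female gametophyte genes (6, median -0.04, mean 0.03), touch and wound genes (7, median 0.10, mean -0.12) and heat shock genes (6, median 0.01) had a downward test, which differs in sign from the mean or the median. Every list member named as fallen or risen lost its call without the wild-type stage 13-14 library, apart from SWEET9, SWEET14, TPS24, TPS11, EXPA8, EXLB1 and GID1A. The members that lost it there also lost it in flower libraries alone, except for WES1 and HAT2. Without a filter HAT2, BPEp and SWEET7 lost it, and SWEET7 did so with a pseudocount of 200 as well.

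In all, 1052 of 17642 probe sets differed in older flowers between arf6 arf8 and wild-type, 504 higher and 548 lower, each with the same sign at both stages (limma, 12 libraries, median SE 0.25), and 4181 had an unadjusted p under the threshold. The median difference of the higher probe sets was 1.32, and that of the lower ones -1.52. With 1 library left out the count was 160 without wild-type stage 13-14, 369 without wild-type stage 11-12, 177 and 458 without arf6 arf8 stages 13-14 and 11-12, 655 and 656 without single-copy stage 1-10 and stem, and 2324 and 2338 without single-copy stages 11-12 and 13-14. It was 247 in flower libraries alone and 2446 without the single-copy libraries of stages 1-10 and 13-14, which stood apart.

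Whether 1 remaining gene copy preserved the wild-type levels was asked in the same older flowers. Against single-copy flowers, arf6 arf8 had less SWEET9 (-4.58), SWEET14 (-4.43), AT1G44970 (-5.23, SE 0.211, adjusted p = 4.72e-05), AT1G30795 (-5.01) and AT1G72290 (-6.44, SE 0.849, adjusted p = 0.00779) and more AT1G16950 (4.33, SE 0.361, adjusted p = 0.00104), HIS1-3 (3.29) and AT4G35690 (2.78). SWEET9 signals in single-copy flowers were 1350 and 5201, beside 1310 and 5520 in wild-type. Wall genes fell here too, namely AT5G48900 (-3.86), AT5G11420 (-3.86) and AT1G70720 (-3.71). So did AT4G19430 (-3.88), AT4G11290 (-3.74) and AT5G45950 (-3.70), and AT2G05540 (3.22), AT1G49500 (3.12), PAP20 (2.74), SFP1 (2.39) and WES1 (2.39) rose. Without the arf6 arf8 stage 13-14 library the calls of HIS1-3, AT1G72290, AT2G05540, AT1G49500, PAP20, SFP1 and WES1 ended (adjusted p of up to 0.179), whereas the other genes named here passed with any library left out. In flower libraries alone the calls of AT5G11420, AT1G49500 and PAP20 ended.

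That comparison called 716 probe sets, 368 higher and 348 lower (limma). Of these, 271 higher and 297 lower were also called against wild-type, where 10.5 and 10.8 would be shared if the calls were independent and 0 were shared on average in 20 simulations without an effect. The simulations leave out the effects and the first expectation leaves out the shared arrays, so neither measures the excess. Part of the excess may come from the arf6 arf8 arrays that both comparisons share, and the data cannot split it. Between single-copy and wild-type flowers 0 probe sets passed (limma, 655 with an unadjusted p under the threshold, smallest adjusted p 0.0675), and 1 passed with quantile normalization or without the single-copy stage 13-14 library. The lists of tapetum and pollen wall genes (median -0.37) and of expansin and XTH genes (median -0.56) both had a camera adjusted p of 0.0408 there, with adjusted p = 0.52 and 0.559 with an estimated correlation. Both calls end when adjusted over all 25 lists written (adjusted p = 0.113). Of 17 added lists 7 passed camera there, among them tapetum and sporogenous genes (median -0.37, adjusted p = 0.000516) and plastid-encoded genes (median -0.30, adjusted p = 0.000248), each with adjusted p = 0.416 with an estimated correlation. By fry 0 of the 26 lists passed there (adjusted p of 0.517, 0.736, 0.478 and 0.478 for these 4). Without the single-copy stage 11-12 library all 4 calls ended (adjusted p = 0.876, 0.876, 0.375 and 0.136). So did those of tapetum and pollen wall (0.476), tapetum and sporogenous (0.284) and plastid-encoded genes (0.157) without wild-type stage 11-12, and that of expansin and XTH genes (0.939) without wild-type stage 13-14. The tapetum and pollen wall call ended also without single-copy stage 13-14 (0.0679) or arf6 arf8 stage 1-10 (0.0539) or stem (0.0514), and both fixed calls did so with quantile normalization (0.0799), without a filter (0.0716), with a filter of 200 in 3 libraries (0.0582 and 0.117) and without the 2 single-copy libraries that stood apart (0.107 and 0.0631). A pseudocount of 200 ended the first (0.173) and one of 16 the second (0.0819). The count of 716 became 84 and 365 without arf6 arf8 stages 13-14 and 11-12, 437 and 442 without single-copy stage 1-10 and stem, 466 without wild-type stage 1-10 or stem, 1330 without single-copy stage 13-14 and 109 in flower libraries alone.

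How the mutants differed from wild-type within each tissue was compared by fold. In stem, arf6 arf8 had more AT1G33790 (10.4-fold), AT3G02910 (9.09-fold), SWEET10 (8.9-fold, signals of 1993 and 179.4) and THI2.2 (8.07-fold), which encodes a thionin. Lower in the arf6 arf8 stem were the anther gene AT1G68875 (31.2-fold, 1627 in wild-type and 3.8 in arf6 arf8), the tapetum gene ATA27 (16.2-fold), AT1G66850 (13.7-fold), AT1G72110 (12.2-fold) and AT5G47550 (11.4-fold). In the same stems 45 of 47 other transcripts abundant in stage 1-10 flowers and dim in the single-copy stem were higher in wild-type than in arf6 arf8. Stage 1-10 flowers of arf6 arf8 had more GILT (6.87-fold) and EXLB1 (5.26-fold) and less AT1G43590 (10.4-fold), AT1G72290 (8.51-fold), AT3G10020 (6.74-fold) and AT1G12010 (4.8-fold). At stages 11-12 AT1G16950 was 29-fold higher and AT1G72290 80-fold lower, and at stages 13-14 AT1G12010, lower in younger flowers, was 18-fold higher and CYP71B31 124-fold, SWEET9 41.6-fold and XTH19 33.4-fold lower. These folds compare single arrays and were not tested.

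**Figure D2:**
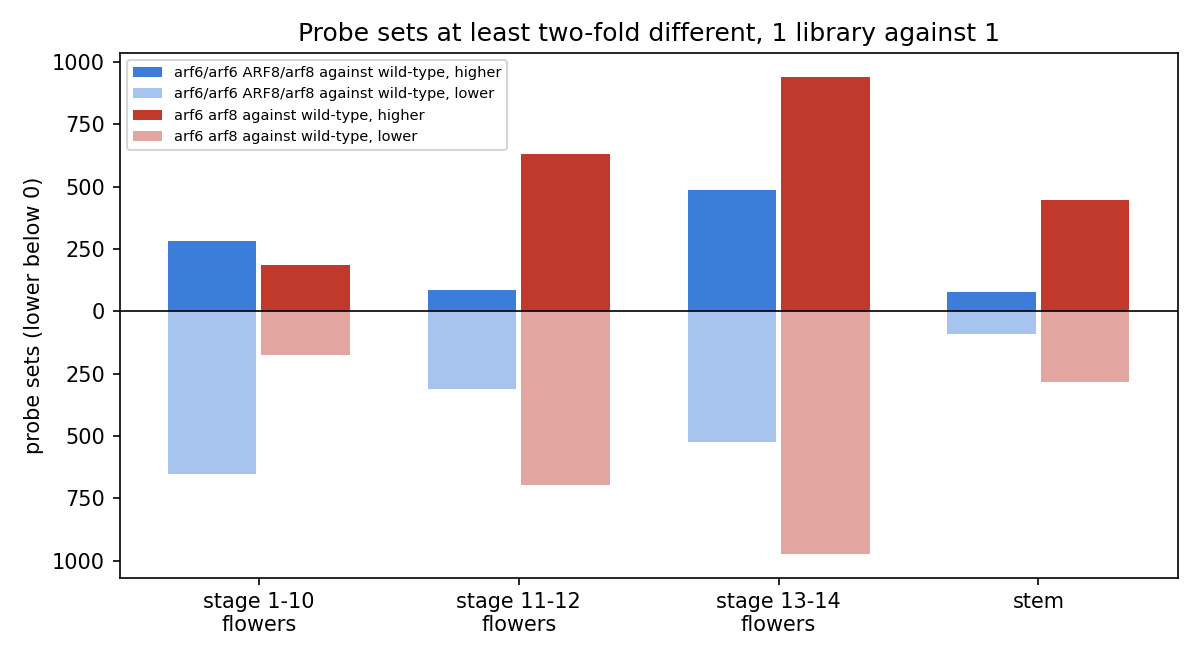
Number of probe sets at least 2-fold higher (bars above 0) or lower (bars below 0) than wild-type in each tissue, for single-copy and arf6 arf8 plants. The arf6 arf8 bars are tallest at stages 13-14, with 941 higher and 972 lower, and the single-copy bars are shortest in stem, with 77 and 89.

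Between arf6 arf8 and wild-type 188 probe sets were at least 2-fold higher and 174 lower in stage 1-10 flowers, 630 and 695 at stages 11-12, 941 and 972 at stages 13-14, and 447 and 285 in stem. Between single-copy plants and wild-type, measured the same way, the numbers were 282 and 654, 87 and 310, 487 and 525, and 77 and 89. In stage 1-10 flowers the total for arf6 arf8, 362, thus lay below that for single-copy plants, 936. In arf6 arf8, 405 probe sets were higher and 387 lower at both older stages, and 6 went opposite ways, where 33.6 and 38.3 would be shared if the stages were independent. That expectation leaves out what the 2 stages have in common, such as their genotypes and bright probe sets, so it does not measure the excess. In all 4 tissues 19 were higher and 22 lower. With quantile normalization the single-copy numbers were 331 and 413 in stage 1-10 flowers and 380 and 632 at stages 13-14.

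In younger tissue, stage 1-10 flowers and stem, the question was whether the double mutation matters outside maturing flowers. The labels give stem no stage, so this group mixes young flowers with another organ. It does not isolate flowers before they mature. EXLB1 rose by 2.69 (SE 0.276, adjusted p = 0.0302), AT3G55920 by 2.34 (SE 0.219, adjusted p = 0.0296), AT3G16330 by 2.02 and AT2G25450 by 1.88. AT5G16920 fell by 1.86 (SE 0.225, adjusted p = 0.0389), from 4433 to 1163 in stage 1-10 flowers, and AT3G50560 fell by 1.79. The added list of 13 tapetum and sporogenous genes had a median of -1.06 with every member below 0, 0 past the test and 8 when adjusted over the list alone (camera adjusted p = 3.62e-12, adjusted p = 0.125 with an estimated correlation). Its median was -0.85 in stage 1-10 flowers and -1.30 in stem, where 45 of 47 other transcripts abundant in stage 1-10 flowers and dim in the single-copy stem were also higher in the wild-type sample than in arf6 arf8. The fixed list of 3 tapetum and pollen wall genes had a median of -0.82, 0 past the test and 2 when adjusted over the list alone (camera adjusted p = 0.00551, adjusted p = 0.232 with an estimated correlation). Cold and dehydration genes had a median of -0.63 (camera adjusted p = 0.0236, adjusted p = 0.741 with an estimated correlation). By fry these 3 lists had an adjusted p of 0.0909, 0.226 and 0.664. The camera call of the first was kept in every alternative, that of the second ended without arf6 arf8 stage 1-10 (adjusted p = 0.106), and that of cold and dehydration genes ended without the wild-type (0.373) or arf6 arf8 (0.347) stem, without a filter (0.0979), in flower libraries alone (0.525) and without the 4 single-copy libraries (0.0592) or the 2 that stood apart (0.0598).

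Altogether 12 probe sets differed in younger tissue, 7 higher and 5 lower (limma, median SE 0.25). With 1 library left out the count was 0 without wild-type stage 1-10, wild-type stem or arf6 arf8 stem, 1 without single-copy stage 1-10 or stem or arf6 arf8 stage 11-12 or 13-14, 2 without wild-type stage 11-12 or 13-14 or arf6 arf8 stage 1-10, and 23 without single-copy stage 11-12 or 13-14, so each of the 6 genes named lost its call without at least 1 library. It was 5 with a pseudocount of 200, 2 without a filter, 0 in flower libraries alone and 1 without the single-copy libraries that stood apart. The calls of all 6 genes named ended without those libraries, and those of all but AT3G55920 without a filter.

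Which genes differed on average over the 4 tissues was asked with 1 difference, which does not test whether the tissues respond alike. EXLB1 rose by 2.62 (SE 0.196, adjusted p = 0.000666), with 2.40, 3.0, 2.1 and 2.98 in stage 1-10, 11-12 and 13-14 flowers and stem, and in single-copy plants it differed by 1.69, 1.69, 0.76 and 1.79. AT3G53980 rose by 2.42 (SE 0.281, adjusted p = 0.00655), AT1G27030 by 1.77 and AT1G25530 by 1.75. AT1G43590, listed as a pseudogene, fell by 2.68 (SE 0.229, adjusted p = 0.00117). Each of these 5 kept its call whichever library was left out, and all but EXLB1 lost it without the 4 single-copy libraries. In flower libraries alone AT3G53980, AT1G27030 and AT1G25530 lost it, and AT3G53980 and AT1G25530 did so without a block for tissue. FMO (2.29), AT3G45680 (1.93), AT3G02910 (1.92) and SWEET10 (1.89, SE 0.271, adjusted p = 0.0133) rose, and EXPA8 (-2.97, SE 0.401, adjusted p = 0.0117), AT5G48900 (-2.96), RXF26 (-2.79), AT5G51950 (-2.75), AT5G50335 (-2.57), AT5G45950 (-2.43), AT4G19430 (-2.37), AT5G47550 (-2.27) and AT1G72110 (-2.05) fell. Each of those 13 lost its call without the wild-type stage 11-12 library and also without the arf6 arf8 one, with an adjusted p of up to 0.195 when 1 library was left out, and each also lost it in flower libraries alone and without the 4 single-copy libraries. Of the 24 genes that the naming rule gives for this difference, only 4 kept their call in every processing alternative. The fit without a block for tissue was among these alternatives.

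Over the 4 tissues 297 probe sets differed, 150 higher and 147 lower (limma, median SE 0.19). The count was 14, 123, 173 and 588 without arf6 arf8 stage 11-12, 13-14, stem and stage 1-10, 16, 31, 116 and 538 without wild-type stage 11-12, stem, 13-14 and 1-10, and 118, 174, 188 and 562 without single-copy stem, 11-12, 1-10 and 13-14. It was 6 in flower libraries alone, 12 without a block for tissue, 177 without a filter and 4 without the 4 single-copy libraries.

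As a reference for flower maturation, stages 13-14 were set against stages 1-10 over all 3 genotypes. The pollen genes RALFL26 (5.47, SE 0.358, adjusted p = 1.88e-05), for a signalling peptide, and PLIM2a (4.96, SE 0.466, adjusted p = 7.5e-05), for an actin-binding protein, rose, as did AT3G26110 (5.54), scpl38 (5.49), AT3G17060 (5.43) and AT1G54070 (5.32). The tapetum genes ATA27 (-7.10, SE 0.667, adjusted p = 7.5e-05) and A9 (AT5G07230, -5.73) fell, as did AT1G68875 (-7.38, SE 0.852, adjusted p = 0.000262), AT1G66850 (-6.43), AT5G62080 (-5.85), LCR66 (-5.68) and AT1G75920 (-5.58). Of 36 pollen genes 23 rose (median 2.13), and of 13 tapetum and sporogenous genes 11 fell (median -3.62). The 24 genes that the naming rule gives for this comparison, which include those named one by one here, kept their calls in every processing alternative and with any library left out. In all, 3300 probe sets differed, 1620 higher and 1680 lower (limma, 3 libraries per stage, median SE 0.22), 1971 without the single-copy stage 1-10 library, 2155 without the arf6 arf8 stage 1-10 library, 2172 without the single-copy libraries of stages 1-10 and 13-14, and 1663 without all 4 single-copy libraries.

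**Figure D3:**
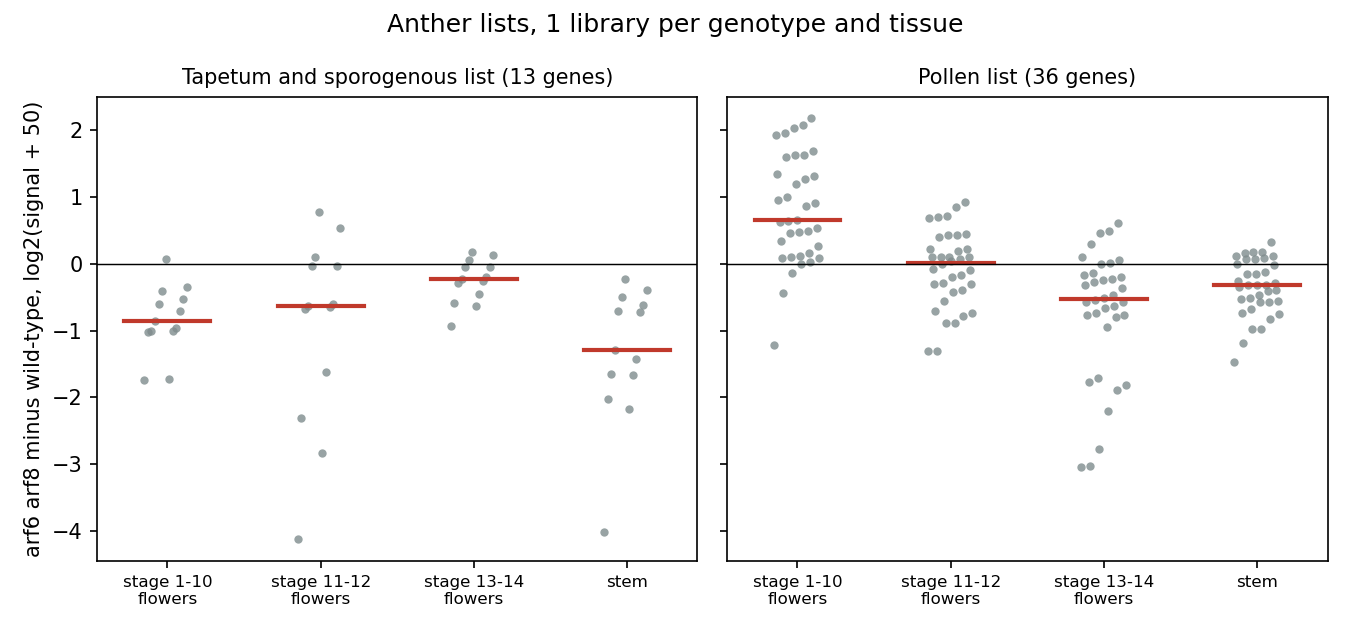
Difference of log2(signal + 50) between arf6 arf8 and wild-type in each tissue for 13 tapetum and sporogenous genes and 36 pollen genes, with a dot for each gene and a line at the median. Tapetum medians are -0.85, -0.64, -0.24 and -1.30 in stage 1-10, 11-12 and 13-14 flowers and stem, and pollen medians are 0.65, 0.01, -0.53 and -0.32.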

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

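The tests of array brightness and of collection stage for the older flower difference, and the fits without single-copy libraries, were chosen only after the result was seen, whereas the counts of splits were planned.

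The arf6 arf8 difference from wild-type depended on tissue for 52 probe sets, 13 with a higher and 39 with a lower effect in older flowers than in younger tissue, by limma's test of the difference itself (1892 with an unadjusted p under the threshold). The older minus younger difference was 4.11 for AT1G16950 (SE 0.51, adjusted p = 0.0275), 3.54 for AT4G35690 (SE 0.329, adjusted p = 0.0085) and 2.74 for AT1G67640. It was -4.36 for SWEET9 (SE 0.534, adjusted p = 0.0261) and -3.39 for SWEET14, the sugar transporter genes, and -3.75 for AT3G25810 and -3.53 for AT5G44630, the terpene synthase genes TPS24 and TPS11. TPS11 signals were 1001 in wild-type and 932.5 in arf6 arf8 at stages 1-10, and 3512 and 102.3 at stages 13-14. The same difference was -4.30 for AT1G75300, -4.27 for AT1G70720, -4.14 for AT1G30795, -4.03 for AT1G76240, -3.76 for AT4G11290, -3.66 for AT1G44970, -3.62 for AT4G12530 and -3.42 for AT1G05450. As lists, 16 SWEET genes (median -0.53, camera adjusted p = 0.00135, adjusted p = 0.325 with an estimated correlation) and 6 expansin and XTH genes (median -1.15, camera adjusted p = 0.00496, adjusted p = 0.592 with an estimated correlation) had a lower arf6 arf8 effect in older flowers than in younger tissue, and so did 36 pollen genes (median -0.41, camera adjusted p = 0.000453, adjusted p = 0.612 with an estimated correlation), 22 genes of the expansin and XTH family (median -0.79, camera adjusted p = 0.000393) and 5 terpene synthase genes (median -0.89, camera adjusted p = 0.00849), the last 2 with adjusted p = 0.491 with an estimated correlation. A higher effect was found for 18 nuclear photosynthesis genes (median 0.36, 18 above 0), 42 plastid-encoded genes (median 0.47) and 13 tapetum and sporogenous genes (median 0.65), with camera adjusted p = 0.000453, 0.000619 and 0.0123, and each with adjusted p = 0.491 with an estimated correlation. Added lists that passed camera numbered 7 of 17. By fry SWEET genes passed (adjusted p = 0.00674), whereas the other lists here had an adjusted p of 0.163 to 0.611. The SWEET call by camera was kept in every alternative. Without arf6 arf8 stage 13-14 the calls of the 6 expansin and XTH genes (adjusted p = 0.396), their larger family (0.0853), pollen (0.152), tapetum (0.132) and plastid-encoded genes (0.0683) ended. Calls also ended without wild-type stage 13-14 for the 6 expansin and XTH (0.0899) and tapetum genes (0.332), without the wild-type (0.168) or arf6 arf8 (0.791, median 0.08) stage 1-10 library for pollen genes, without the wild-type stem for tapetum (0.218), nuclear photosynthesis (0.0847) and plastid-encoded genes (0.218), and without the arf6 arf8 stem for plastid-encoded genes (0.413). In flower libraries alone those of terpene synthase (0.0667), tapetum (0.151), nuclear photosynthesis (0.137) and plastid-encoded genes (0.566) ended, the terpene synthase call ended without a filter (0.0762, median -0.01) and without the 4 single-copy libraries (0.051) or the 2 that stood apart (0.0504), and the calls of the 6 expansin and XTH genes (0.0603) and tapetum genes (0.0565) ended with a filter of 200 in 3 libraries. The count was 0 without the wild-type or arf6 arf8 library of stage 1-10 or stem, 7 and 12 without wild-type stages 13-14 and 11-12, 22 without single-copy stage 1-10 or stem, 24 and 79 without arf6 arf8 stages 13-14 and 11-12, and 132 and 136 without single-copy stages 11-12 and 13-14. It was 14 without a filter, 33 with a pseudocount of 16, 0 in flower libraries alone and 30 without the single-copy libraries of stages 1-10 and 13-14. The call of every gene named here ended without each of the 4 wild-type and arf6 arf8 libraries of younger tissue, left out 1 at a time, with an adjusted p of up to 0.362 for AT5G44630. Those of SWEET9, SWEET14, AT3G25810, AT4G12530 and AT5G44630 ended without the single-copy libraries as well. With all libraries in the fit, only 6 of the 15 genes named here kept their call in every processing alternative.

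A pattern to follow up is that 1052 probe sets, SWEET9, EXPA8, TPS11 and TPS24 among them, differed in older arf6 arf8 flowers. The wild-type arrays of these stages were brighter at the 99th percentile (7392 and 7418) than those of arf6 arf8 (6740 and 6710), but quantile normalization, which makes the distributions equal, left 1001 of the 1052 called in the same direction (95.2%) among 1222 calls, which argues against brightness as the whole cause. In single-copy flowers, whose stage 1-10 and 13-14 arrays stood apart, the mean of stages 11-12 and 13-14 was set against stages 1-10. Of the 548 fallen genes 160 (29.2%) rose at least 2-fold and 46 (8.39%) fell (3.48 to 1). Of the 504 risen genes 59 (11.7%) rose and 5 (0.99%) fell (11.8 to 1). Over all 17642 tested, 1435 (8.13%) rose and 853 (4.84%) fell (1.68 to 1). By this mean most called genes did not move 2-fold, but a rise and a later fall can cancel in it. Fallen genes rose and fell in 207 and 8 cases from stages 1-10 to 11-12 in wild-type and 184 and 22 in single-copy flowers, and in 57 and 53 and 51 and 102 from stages 11-12 to 13-14, and risen genes in 15 and 34 and 33 and 6, and then 55 and 6 and 62 and 13, so single steps do not all point one way and a younger or an older collection stage stays open for both directions, as it does by the pollen list's medians of 0.65, 0.01 and -0.53 over the 3 stages and by the probe sets that differed 2-fold in arf6 arf8 and wild-type, 1636 and 1364 from stages 1-10 to 11-12 and 544 and 1019 from stages 11-12 to 13-14. The tapetum list, which falls with stage, had a median of -0.636 at stages 11-12, but single-copy flowers had -0.806 against the same wild-type library, so it leaves the stage open, and the double mutation that the design names, organs that mature at different rates and a difference between the plants sampled stay open too.

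The count of 297 probe sets over 4 tissues was reached by 1 of the 35 splits of the 8 wild-type and arf6 arf8 libraries, the real one, and the highest of the others gave 0. Only 8 of these splits keep the libraries matched by tissue, which is too few for a share under 0.05. The 10 splits of the stage comparison (3300 genes, highest other 0) are too few for it as well.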

How the results depend on the processing

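No reversal of direction was counted among named genes, or among the lists of older arf6 arf8 flowers, in the alternatives run. A change of sign counted as a reversal only if the reported or the alternative fit passed the threshold. Uncalled genes and lists are therefore not covered. The balance of calls did turn, from 504 higher and 548 lower to 1347 and 1099 without the single-copy libraries of stages 1-10 and 13-14, and from 368 and 348 to 11 and 73, against single-copy flowers, without arf6 arf8 stage 13-14. Without counting libraries left out in turn, counts stayed within 1.5 times of the reported one in 85 cases and moved further in 42, and calls of named genes kept their side of the threshold in 3397 cases, were lost in 199 and gained in 45, with 4015, 401 and 48 when 1 library was left out. Lists in older arf6 arf8 flowers kept their side of the threshold in 247 cases and lost a call in 7. With 1 library left out they kept it in 299, lost a call in 10 and gained a call in 3. For single-copy against wild-type, younger tissue and older minus younger in turn, lists kept their side in 206, 242 and 243 cases and lost a call in 22, 4 and 9. With 1 library left out they kept it in 284, 303 and 292, lost a call in 22, 3 and 13 and gained a call in 4, 5 and 7. With all other alternatives lists gained a call in 6 cases in younger tissue and in 2 for older minus younger. Cases that kept their side include genes and lists called in neither fit. In older arf6 arf8 flowers only 1 of the 9 fixed and 7 of the 17 added lists had a camera call to lose. Called named genes kept the call in every processing alternative in 39 of 44 cases (older flowers), 21 of 24 (against single-copy flowers) and 24 of 24 (stages). They did so in 1 of 6 (younger tissue), 6 of 15 (older minus younger) and 4 of 24 (over 4 tissues). Lists reversed in 5 cases: for single-copy against wild-type, pollen genes without single-copy stage 11-12 (median -0.15 as reported, 0.0833, adjusted p = 0.94, and -0.43 without single-copy stage 13-14) and the expansin and XTH family without wild-type stage 13-14 (-0.29, 0.0274, adjusted p = 0.411, and -0.58 without wild-type stage 11-12), and in younger tissue pollen genes without arf6 arf8 stage 1-10 (0.16, -0.33, adjusted p = 0.00442, and 0.73 without the arf6 arf8 stem) and, in flower libraries alone, GH3 (0.20, -0.50, adjusted p = 0.048) and plastid-encoded genes (-0.13, 0.18, adjusted p = 0.0484). Leaving a library out gives an arm a lone sample in a phase, whose spread is assumed to be that of the other groups. Values without rescaling moved nothing by construction, so they say nothing about stability. The fits without single-copy libraries were chosen after seeing the data. The single-copy difference has no value without the 4 single-copy libraries. The labels give no replicate numbers, so libraries were matched by tissue alone. Signals well under the pseudocount of 50 lie near background, so folds of dim transcripts are understated. Except for fewer libraries and a larger number of genes tested, which follow from the alternative itself, the cause was not tested.

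In flower libraries alone the counts were 247 (reported 1052, arf6 arf8 against wild-type in older flowers), 109 (reported 716, against single-copy flowers), 0 (reported 12, younger tissue), 0 (reported 52, older minus younger) and 6 (reported 297, over 4 tissues). Without a filter they were 2, 14 and 177 for the last 3 of these. A pseudocount of 200 gave 5 in younger tissue, a pseudocount of 16 gave 33 for older minus younger, and no block for tissue gave 12 over 4 tissues. Quantile normalization gave 1 for single-copy against wild-type (reported 0). Without the single-copy libraries of stages 1-10 and 13-14 the counts were 2446 (older flowers), 2182 (against single-copy flowers), 1 (younger tissue), 30 (older minus younger) and 2172 (stages). Without all 4 single-copy libraries they were 2459, 1, 30, 4 (over 4 tissues) and 1663 (stages).

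With each library left out in turn the counts ranged from 160 to 2338 (older flowers), 0 to 1 (single-copy against wild-type), 84 to 1330 (against single-copy flowers), 0 to 23 (younger tissue), 0 to 136 (older minus younger), 14 to 588 (over 4 tissues) and 1971 to 3088 (stages, reported 3300). Of the 9 lists, 0 to 2 passed camera (reported 1): 0 without arf6 arf8 stage 13-14 and 2 without arf6 arf8 stage 11-12, where late pollen genes passed too (median -0.84, adjusted p = 0.00573).

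With a pseudocount of 200, the 2-fold counts of arf6 arf8 against wild-type were 164, 770, 1129 and 366 in stage 1-10, 11-12 and 13-14 flowers and stem (reported 362, 1325, 1913 and 732), and those of single-copy plants 318, 147, 386 and 68 (reported 936, 397, 1012 and 166). With a ratio of 3 they were 98, 457, 727 and 242, and 82, 71, 168 and 48. With a brighter signal of 500 or more they were 240 in stage 1-10 flowers and 448 in stem for arf6 arf8, and 248 at stages 11-12 and 87 in stem for single-copy plants.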

Other observations

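The tests on the single-copy libraries, and the genes shifted in both mutants, were chosen only after the result was seen, whereas the tests of buds in stem and of graded gene copies were planned.

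Anther transcripts in arf6 arf8 flowers differed from wild-type in a way that varied with stage. The 36 pollen genes lay above wild-type in stage 1-10 flowers (median 0.65, percentile 100 among matched random lists, 32 members above 0), at 0.01 at stages 11-12, and below it at stages 13-14 (median -0.53, percentile 0, 29 members below 0). RALFL25, for a pollen signalling peptide, read 48.2 in wild-type and 265.7 in arf6 arf8 at stages 1-10, and 4282 and 483.1 at stages 13-14. PLIM2a read 64.9 and 305.3, then 5133 and 2928. The 13 tapetum and sporogenous genes lay below wild-type in stage 1-10 flowers (median -0.85, percentile 0) and at stages 11-12 (median -0.64, percentile 0), and single-copy flowers had medians of -0.44 and -0.81. ATA27, a tapetum gene, read 10040, 2878 and 63.2 in wild-type over the 3 stages, 11510, 433.8 and 3.9 in single-copy flowers, and 7888, 118.1 and 9.1 in arf6 arf8. These list medians compare single arrays, and plastid-encoded genes in the same flowers had medians of 0.18, 0.08 and 0.48. The random lists were matched on mean signal alone and drew genes independently, whereas pollen genes varied together (estimated correlation 0.448). The percentiles therefore do not tell how often a list of genes that vary together would move as far between single arrays.

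A few transcripts, 3 higher and 2 lower, differed at least 2-fold from wild-type in both mutants and in all 4 tissues. Both mutants were set against the same 4 wild-type arrays, so how much of this agreement is owed to those arrays is not known. In single-copy plants 3 were higher and 2 lower in all tissues and in arf6 arf8 22 and 29 (signal of 200 or more in any of the 12 libraries), of which 0.00374 and 0.00329 would be shared if independent, and 0.05 and 0 were shared on average in 20 simulations without an effect. SWEET10, a sugar transporter gene, was higher by 1.11 to 3.16 (log2), AT3G55920 by 1.34 to 2.46 and AT3G53980 by 1.46 to 3.64. AT3G55920 read 2 to 4.4 in the wild-type libraries and 87.2 to 250.2 in those of both mutants. AT1G43590, listed as a pseudogene, was at -3.38 to -1.76, and a probe set for which the table lists no gene at -4.56 to -2.57. The medians over tissues in single-copy and arf6 arf8 plants were 1.44 and 1.60 for SWEET10, 1.94 and 1.91 for AT3G55920, and -3.01 and -2.80 for AT1G43590.

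The single-copy libraries of stages 1-10 and 13-14 differed from wild-type in more probe sets than that of stages 11-12. With quantile normalization the count was 744 at stages 1-10 (331 higher and 413 lower, from 282 and 654, with 626 shared) and 1012 at stages 13-14 (380 and 632, from 487 and 525, with 854 shared), beside 352 at stages 11-12 and 165 in stem, which argues against array brightness as the whole cause but not as a part of it. A genotype effect shared by both stages would by itself give a positive correlation of the single-copy differences across genes. Pearson's r between stages 1-10 and 13-14 was -0.427 (genes are not independent replicates, 1 of 6 such correlations computed), and -0.399 with quantile normalization. It was 0.562 between stages 1-10 and 11-12 and -0.258 between stages 11-12 and 13-14. For arf6 arf8 it was 0.0844 between stages 1-10 and 13-14 and 0.721 between stages 11-12 and 13-14. Opposite technical differences of the single-copy arrays of stages 1-10 and 13-14 could hide a shared effect, so r cannot exclude one. Both arrays were the extremes of the 12 on control transcripts added to each sample and on 25S rRNA, the highest at stages 1-10 (creX 10266.6, 25S rRNA 179.8) and the lowest at stages 13-14 (4148.2 and 41.5), so a technical difference of these arrays stays open. Different mean ages of the sampled flowers may contribute, and this and a genotype effect that differs between stages were not tested.

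Tapetum transcripts were higher in the wild-type stem than in both mutant stems, with a median of -1.30 in arf6 arf8 and -0.80 in single-copy stems over 13 genes. ATA27 read 801.9 in wild-type stem, 59 in single-copy stem and 2.6 in arf6 arf8 stem, and AT1G68875 read 1627, 4.5 and 3.8. Young flower buds in the wild-type stem sample were considered with 47 other transcripts abundant in stage 1-10 flowers and dim in the single-copy stem. They also had an excess over the arf6 arf8 stem, with a median of 3.1% of their wild-type flower level (45 above 0), beside 4.99% for 10 tapetum genes (1.01 to 12.9). These 47 were chosen by signal with only the listed genes left out, so other anther genes can be among them. A loss of anther transcripts alone could give such an excess too, so buds stay open and the test cannot decide. Late flower transcripts had a median excess of 0.363% of their stage 13-14 level over 56 transcripts. A genotype effect on these transcripts in stem stays open and untested.

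The hypothesis that single-copy flowers lie between wild-type and arf6 arf8 in general was tested on the 1913 probe sets with a 2-fold difference in arf6 arf8 at stages 13-14. Signed by that direction, their single-copy difference at stages 11-12, which shares no library with their choice, had a median of -0.0392 with 46.6% on that side, beside 0.912 for arf6 arf8 at the same stages, which shares the choice's genotype. The result was negative for these genes as a set. Single genes such as EXLB1 had intermediate values, with 1.69 in single-copy and 3.0 in arf6 arf8 flowers at stages 11-12.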
